A study of Saccharomyces cerevisiae with 79 samples.

How the data were processed

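Newly made RNA of Saccharomyces cerevisiae was measured by multiplexed primer extension sequencing of targeted introns after 4-thiouracil labelling, with Schizosaccharomyces pombe RNA added as a spike-in. Per the labels, the WT and prp2-1 series had spike-in RNAs transcribed in vitro, and the WT_30 series had total labelled S. pombe RNA. The 23 deposited tables each list 308 introns and 5 spike-in RNAs for 79 samples. Reads were aligned with STAR 2.7.2b to build R64, per the submitters' processing notes, which do not describe how reads were then assigned to introns.

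Counts of all reads, unspliced reads, lariat intermediate reads and reads ending between branch point and 3′ splice site were deposited as whole numbers, per the file headers, without scaling. Estimated counts of the lariat intermediate and of RNA before the first step were derived by the authors from these, by sharing out the reads that end between branch point and 3′ splice site; the deposited values met this relation in 11582 of 11582 cells, within a relative tolerance of 0.0001 for the lariat intermediate and 0.001 for RNA before the first step. Signal values in the deposited normalized tables are the raw values multiplied by a factor, less the mean of the 0 s libraries and with negative values set to 0. This held in 8505 of 8505 cells checked for unspliced reads in WT (relative tolerance 1e-06) and 5591 of 5591 in WT_30 (the wider tolerance 0.002). The factor was the same in all replicates of a nominal time, for example 8.2161 in each WT library at 150 s. The splicing index in the deposited tables is a ratio of unspliced to spliced reads, per the file headers, and correlated with the log2 ratio computed here over 264 introns (r = 0.968). Tests used the whole-number counts. Lariat reads and reads ending past the branch point are part of the unspliced reads (12833 of 12833 cells), and unspliced reads part of all reads (19093 of 19093 cells), so spliced reads were taken as all reads less unspliced reads.

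Of the 29 prp2-1 samples 11 were used: the first time course and the 0 s library of the second. The column numbers of the prp2-1 tables and the numbers in the sample titles disagree beyond these. The columns lack number 12 and the titles lack the 120 s library of replicate 2, so a shift by 1 is a possible reading, but columns were not assigned by order. Hence 18 columns in each of 10 tables (180 in all) could not be assigned to a sample with certainty and were not used here. The comparison planned as 3 against 3 time courses therefore became 3 WT courses against 1 prp2-1 course, in which the lone course is assumed to vary as the WT courses do. All 30 WT and all 20 WT_30 libraries were used, which gives 61 libraries. Median depth was 3867282 reads in WT, 1413604 in prp2-1 and 7311843 in WT_30. Between replicate libraries, chi-squared per degree of freedom over introns ran from 7.68 to 2836 in 41 pairs, so spread exceeds counting error, and no libraries were duplicates. Counts come from PCR-amplified reads without molecular identifiers. WT courses correlated with each other across introns at 0.981 to 0.988 (Pearson).

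The time course was the unit of replication. For each course, counts were summed over 150, 210, 300, 390, 540, 720 and 990 s, over early (150, 210 and 300 s) and late (540, 720 and 990 s) windows, or, against WT_30, over 90, 120, 150 and 300 s. Unspliced and spliced reads, or lariat and other unspliced reads, entered edgeR 4.0.16 as 2 columns per course with a term for each course (or course and window), and the interaction of group and read state was tested by the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Library sizes were the totals of both columns, without TMM. Introns needed a mean of 20 unspliced and 100 total reads, or 20 unspliced and 5 lariat reads. Labelled RNA was tested on all reads of a target with TMM factors. For late against early in prp2-1 there was 1 course and so no test. Late and early windows of a WT course come from the same time course, per the labels, and their deviations correlated at 0.648, 0.374 and 0.618, so they are pairs, and a fit with the course as a block was run beside the fit reported.

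The apparent rate k was fitted per intron and course to the unspliced share u(t) = (1 - exp(-kt))/(kt) over all times after 0 s, by least squares on log2 u with a pseudocount of 0.5 reads and at least 4 times. It assumes constant synthesis, no decay, no lag and no unlabelled background; the lifetime is its inverse. Rates were compared with limma 3.58.1. Class differences and feature correlations used 100000 permutations over introns. Intron length, splice site and branch sequences were read from the R64 genome for 258 introns, with the last match to TACTAAC taken as the branch point, and mismatches were counted against GTATGT and TACTAAC. Ribosomal protein introns number 103.

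The lists were fixed before the data were examined: ribosomal protein, meiotic, self-regulated, cytoskeleton, secretory, ubiquitin pathway, mitochondrial, RNA processing and translation factor genes, and genes with more than 1 intron. The lists by function were set by hand. Some members, such as ARP9 in the cytoskeleton list and GIM5 in the secretory list, do not belong there by function. They were tested with camera at a preset correlation of 0.01 and with an estimated one. Genes are named by a rule fixed at the same time: in each comparison the 8 highest and 8 lowest changes that passed without overlap between the groups (5 and 5 for late against early and for rates), a fixed set (ACT1, YRA1, RPL30, RPS14B, DBP2, SUS1, MTR2, TUB1, TUB3, ASC1 and GCR1), and up to 4 members of each list by size of change. Alternatives fixed beforehand numbered 76. They covered DESeq2 1.42.0, limma on ratios averaged over times, TMM or other scalings, no filter or minimums raised 5 times, other time windows, a pseudocount of 1, a lag of 60 s, times up to 400 s, background subtraction, and leaving out each replicate. Further alternatives were added after the data were seen: the deposited splicing index, times without the 300, 390 and 540 s libraries, thinning to 458437 reads per library, and leaving out reads that end past the branch point. A further test, of 1 technical explanation, is not reported here.

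The tests were tried on simulated data with 60 changed introns. Counts varied with a dispersion of 0.17, except for rates, where they varied by counting error alone. Libraries were drawn independently, so early and late sums of a simulated course were not pairs, unlike those of the data. For unspliced reads in prp2-1 against WT, 26.7% of introns changed by a log2 of 1 and 93.1% of those changed by 2 were found, and for the lariat intermediate 0% and 60.7%. Late against early in WT gave 23.3% and 89.3%, WT_30 against WT 26.7% and 100%, and labelled RNA 73.3% and 100%. Rates gave 90% and 100%, which cannot be set beside the others, since no spread between courses was simulated for them. At most 1.37% of unchanged introns were called in any of these. R 4.3.3 was used for tests, and Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 for tables and figures.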

Results

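Splicing was followed in budding yeast after 4-thiouracil, a uracil analogue that is built into newly made RNA, was added to growing cultures. Labelled RNA was pulled down and read by multiplexed primer extension sequencing (MPE-seq), in which primers placed downstream of chosen introns give reads that show whether the intron is still present. The tables hold 308 targeted introns and 5 spike-in RNAs. For each intron they give all reads, the unspliced reads, and, among the unspliced reads, those assigned to the lariat intermediate, the product of the first chemical step that has not yet gone through the second. The wild-type strain BY4741, called WT here, was sampled in 3 time courses of 10 libraries each, at nominal labelling times from 0 to 990 s. The strain prp2-1 carries an allele of PRP2, which encodes the DEAH-box ATPase that acts on the assembled spliceosome just before the first step. Of this strain, 11 libraries are used, which make up 1 full time course and the 0 s library of another. A further series, also labelled BY4741, carries the label WT_30 and has 2 time courses of 10 libraries, with times up to 3600 s. Beyond its times and another kind of spike-in RNA, the labels do not say what sets it apart. They give no growth temperature for any series.

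Libraries held 414908 to 8130197 reads in WT and 4155116 to 11674413 in WT_30. The labelled prp2-1 libraries held 388817 to 4440617 reads, and the prp2-1 libraries at 0 s held 48248 and 77751. Unlabelled RNA carried through the pull-down sets a background, which the 0 s libraries show. It was subtracted only in an alternative fit of the rates, so the shares and changes reported here include it. At 0 s the median intron had 3.54% ± 0.417 unspliced reads in WT (SD, n = 3) and 3.92% ± 1.39 in WT_30 (SD, n = 2). In prp2-1 replicates 1 and 2 the median at 0 s was 8.33% and 7.14%. The median per intron was 13 and 20 reads in these libraries, and 1 unspliced read in each. So few reads do not give a reliable share, and the prp2-1 background cannot be set beside that of WT. The replicates are time courses, because the libraries of a course follow each other in time. Nothing in the labels says that courses came from separate cultures, so p-values measure the spread between these courses, which may be technical. Counting intervals given for the prp2-1 course are 95% Wilson intervals and cover counting error alone.

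The first comparison asked whether the unspliced share of labelled RNA falls as labelling goes on in WT, by setting the sums over 540, 720 and 990 s against those over 150, 210 and 300 s. The unspliced share of UBC9, the SUMO-conjugating enzyme, fell from 7.55% ± 3.40 to 0.854% ± 0.226 (SD, n = 3). LSM7, a subunit of the ring that binds U6 RNA, fell from 13.3% ± 1.72 to 2.61% ± 0.411. For RPL39, a ribosomal protein gene, it fell from 1.57% ± 0.162 to 0.294% ± 0.0849, and for ACT1, the actin gene, from 22.6% ± 3.25 to 10.7% ± 2.06. In contrast, GCR1, a transcription factor of glycolytic genes, had 75.8% ± 3.36 early and 79.4% ± 3.66 late and did not pass the test. MTR2, which encodes an mRNA export factor, had 87.4% ± 0.177 and 87.8% ± 0.360 and did not pass either, but 99.1% of its unspliced reads ended between the branch point and the 3′ splice site, and without them it had 6.96% ± 1.21 and 5.79% ± 1.16. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 250 of 275 introns fell and 4 rose, with a median log2 change of -1.52.

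Besides UBC9 and LSM7, the strongest falls without overlap between the windows were in EFM5 intron 2 (log2 change -2.76 ± 0.29, SE), RPS25A (-2.76 ± 0.38) and YPR170W-B (-2.61 ± 0.22). Introns of ribosomal protein genes fell in 100 of 103 cases, and none of them rose. The count adjusted over the list alone was also 100. All 19 tested introns of the secretory list fell, among them SFT1 (-2.26) and SNC1 (-2.19), 2 SNARE genes. All 8 ubiquitin pathway introns fell too, for example UBC5 (-1.98). In the mitochondrial list 5 of 6 fell, with COX4 at -2.19. In the cytoskeleton list 9 of 10 fell, with ARP9 at -1.94 and ACT1 at -1.29, although relative to the typical intron none of its introns was lower and 1 was higher. All 19 introns of genes with more than 1 intron fell, and both introns of SUS1, a subunit of the SAGA complex, were among them, at -1.01 for the first and -1.15 for the second. Among translation factors all 3 fell, with ASC1 at -2.35 and TEF4 at -2.10. RNA processing genes fell in 8 of 10 cases, and relative to the typical intron 3 were higher and 1 lower. Of the 6 genes known to control their own splicing or expression, 5 fell, including DBP2 (-1.61), RPL30 (-1.34) and RPS14B (-0.87), whereas YRA1 gave -0.36 and did not pass; relative to the typical intron 2 of the 6 were higher and none lower. TUB3 fell by 1.38 on the log2 scale and TUB1 gave -0.44 without passing. Meiotic genes went both ways, with 2 of 4 falling and SAE3 rising (1.84), and relative to the typical intron 2 were higher and 1 lower. The risers YPR202W (2.27) and YOR318C (0.73) passed without overlap between windows, but YPR202W lies in a subtelomeric family of near-identical copies and its reads are uncertain. The remaining riser, YDR535C (0.85), is named after its values were seen. No intron rose with the count minimums raised 5 times or without WT replicate 1, and DESeq2 gave 1 riser. Leaving out WT replicate 2 or 3 gave 2 risers each, limma gave 4, and the fit with the course as a block gave 6. Groups did not overlap for 248 introns, or 90.2%, where chance gives 10%.

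These falls are on the scale of the reads themselves. Scaling each read state by TMM, which sets the typical intron to 0, moved the median from -1.52 to -0.01 and left 17 introns lower and 39 higher than the typical intron. It is the scale meant above by relative to the typical intron. Under it 7 ribosomal protein introns were lower and 3 higher, 4 multi-intron introns lower and 2 higher, 2 secretory introns lower and none higher, 1 ubiquitin pathway intron lower, 1 mitochondrial intron lower and 1 higher, and no translation factor passed. ACT1, both SUS1 introns, TUB3, RPL30 and RPS14B changed sign.

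Per library, the median unspliced share in WT was 15.5% ± 1.31 at 150 s, 10.9% ± 0.642 at 210 s, 5.88% ± 0.746 at 540 s and 3.69% ± 0.602 at 990 s (SD, n = 3). In ribosomal protein introns it was 3.98% ± 0.491 at 150 s and 0.553% ± 0.164 at 990 s, against 24.6% ± 1.95 and 6.94% ± 0.906 in the other introns. The share assigned to the lariat intermediate was 15.2% ± 2.13 of unspliced reads in the median intron at 150 s and 16.8% ± 1.19 at 990 s. The intron of HAC1, which is removed by the endonuclease Ire1 and a ligase instead of the spliceosome, was looked at after its values had been seen. Its unspliced share was 67.6% ± 2.25 early and 67.1% ± 1.91 late.

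**Figure D1:**
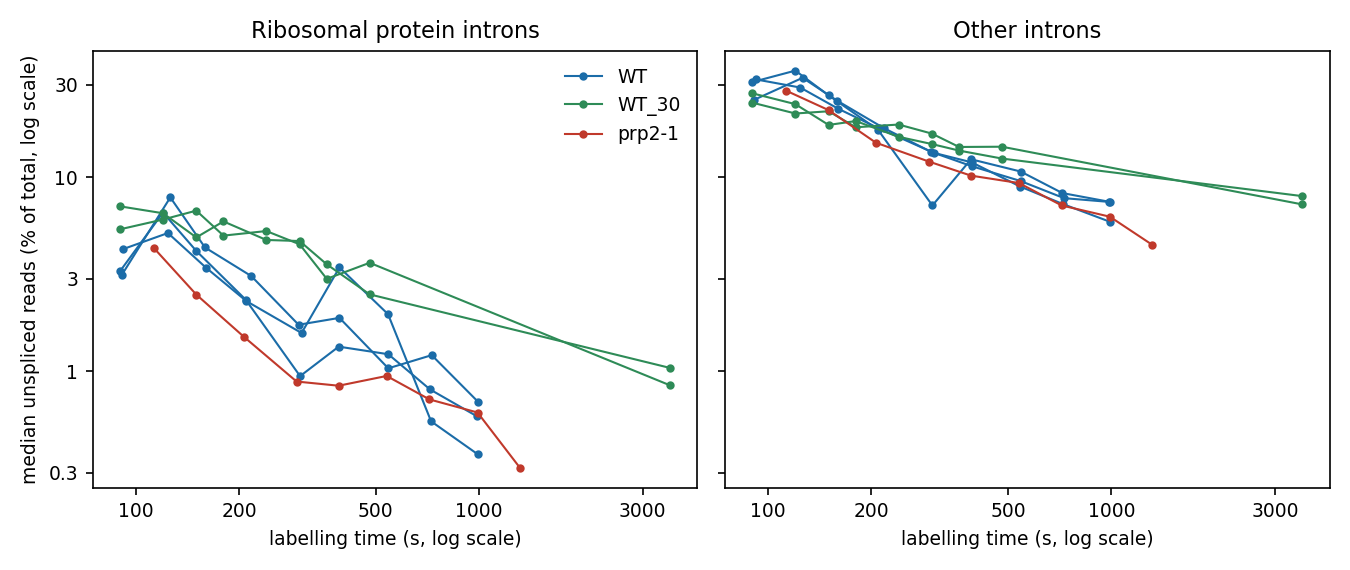
Median unspliced reads as a percent of all reads of an intron (log scale) against labelling time in seconds (log scale), for ribosomal protein introns on the left and other introns on the right. Each line is a time course (3 WT, 1 prp2-1, 2 WT_30), and WT ribosomal protein introns go from 3.98% at 150 s to 0.553% at 990 s.

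Transcript-specific differences within WT were examined next. Ribosomal protein introns, which together take a large part of yeast's spliceosome activity, carried far fewer unspliced reads than other introns. Over the 7 times from 150 to 990 s, the median share was 1.58% in 103 ribosomal protein introns and 11.8% in 179 others. The difference of medians on the log2 ratio scale was -3.08 ± 0.09 (SD, n = 3 courses), and a two-sided permutation test of the class labels over introns gave p = 1e-05, the smallest that 100000 resamples can give. Against the 87 other introns with totals in the same range it was -2.65 ± 0.04. The gap was also present without label. In the 0 s WT libraries the median share was 0.3003% in ribosomal protein introns and 10.6% in the others (mean of 3 libraries). In those of WT_30 it was 0.961% and 8.22% (mean of 2 libraries). The WT values at 0 s rest on few unspliced reads per intron. The class difference is therefore not particular to newly made RNA. The lariat intermediate made up 21.7% of unspliced reads in the median ribosomal protein intron and 15.1% in the others, a log2 difference of 0.71 ± 0.15 (SD, n = 3 courses) with a permutation p of 0.0882. Without a filter on low counts this difference was 0.94 with a permutation p of 0.0160, and without WT replicate 3 it was 0.74 with a permutation p of 0.0387, but with the count minimums raised 5 times it was 0.26 (permutation p = 0.427) and over the late times 0.36 (permutation p = 0.172). Introns are not independent replicates, and these p-values describe this set of introns.

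An apparent lifetime of unspliced RNA was fitted to each intron from its shares over all labelled times. Its median over introns was 24.7 s, 25.7 s and 27.5 s in the 3 WT courses. Ribosomal protein introns had medians of 5.39, 5.57 and 6.22 s, and the other 180 introns 42.4, 44.9 and 45.6 s. The fit assumes no unlabelled background, in which the same class gap was seen. How much of this difference belongs to newly made RNA was not tested. The shortest lifetimes were in ribosomal protein genes: RPS6B (0.792 s ± 0.282, SD, n = 3), RPS18B (0.793 s ± 0.171), RPL6B (0.922 s ± 0.243), RPS6A (0.926 s ± 0.231) and RPL7A intron 1 (1.06 s ± 0.174). Such values lie far below the shortest labelling time, and reads of close paralogs such as RPS6A and RPS6B may be shared, so they neither time nor rank these introns. At the other end were the subtelomeric YPR202W (32273 s ± 3086) and YHL050C (5452 s ± 784), the meiotic helicase gene HFM1 (3322 s ± 2112), MTR2 (2001 s ± 365) and YDR535C (1829 s ± 511). Most unspliced MTR2 reads ended between the branch point and the 3′ splice site.

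**Figure D2:**
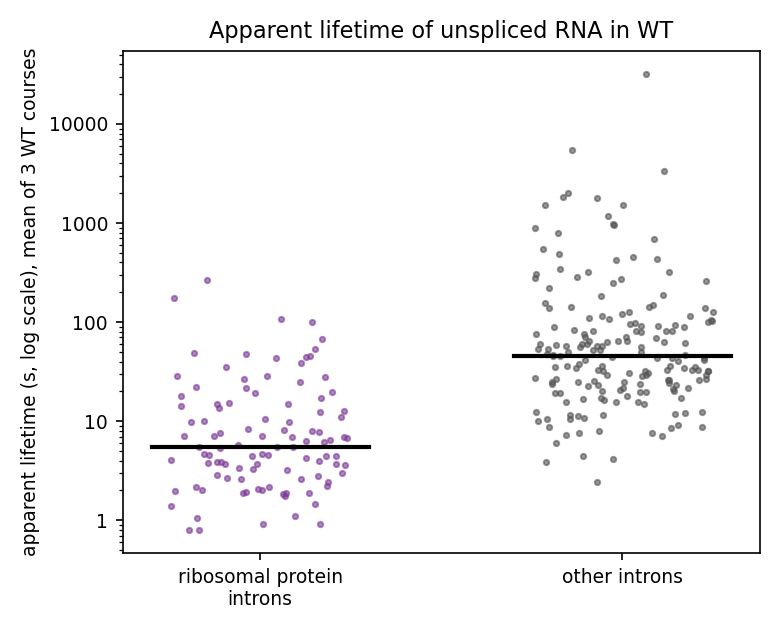
Apparent lifetime of unspliced RNA in seconds (log scale, mean of 3 WT courses) for 103 ribosomal protein introns and 180 other introns. Each point is an intron and the bar is the median; ribosomal protein introns lie lower as a group.

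The lariat share of unspliced reads spanned nearly the whole range. Among introns with a mean of at least 20 unspliced and 5 lariat reads, it was highest in RIM1, a mitochondrial single-stranded DNA-binding protein gene (92.2% ± 0.692, SD, n = 3), RPS7A (86.7% ± 3.74), RPL33B (86.2% ± 2.99), the ribosome biogenesis GTPase gene NOG2 (83.6% ± 3.20) and CGI121 (83.3% ± 5.29). The lowest shares among the same introns were in MTR2 (0.223% ± 0.0450), RPP1B (0.383% ± 0.167), BMH2 (0.471% ± 0.206), UBC13 (0.477% ± 0.152) and SCS22 (0.564% ± 0.183). Without reads that ended between the branch point and the 3′ splice site these became 23.7% ± 1.85 in MTR2, 1.32% ± 0.473 in RPP1B, 1.15% ± 0.593 in BMH2, 3.94% ± 1.24 in UBC13 and 0.567% ± 0.184 in SCS22. Counted from the lowest share, SCS22 then ranked 1 and BMH2 5. RPP1B (rank 9), UBC13 (rank 30) and MTR2 (rank 128) were no longer among the 5 lowest. At the other end the order became CGI121 (94.5% ± 1.02), NOG2 (93.9% ± 1.03), RIM1 (93.8% ± 0.369), RPL33B (90.3% ± 2.57) and SUS1 intron 2 (90.3% ± 1.74). RPS7A (88.7% ± 3.75) was no longer among the 5 highest. In build R64 the RIM1 intron spans chromosome III 173116 to 173198 on the minus strand and is 83 nt long, and the RPS7A intron spans chromosome XV 505938 to 506338 on the plus strand and is 401 nt long. Both begin with GTATGT and hold the branch sequence TACTAAC.

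Across introns, 5 sequence and abundance features were set against 2 measures, which makes 10 pairs, with Benjamini-Hochberg adjustment over them. The apparent rate rose with log10 intron length (rho = 0.41, permutation p = 1e-05, adjusted p = 3.33e-05; r = 0.33, permutation p = 1e-05, adjusted p = 3.33e-05; 237 introns). Within ribosomal protein introns it did not pass (rho = -0.15, permutation p = 0.171; 85 introns). Within other introns rho was 0.02 (permutation p = 0.827; 152 introns) and r ran the other way (r = -0.22, permutation p = 0.00559, adjusted p = 0.0140). Introns with more mismatches to the branch sequence had lower rates (rho = -0.35, permutation p = 1e-05, adjusted p = 3.33e-05; r = -0.32, permutation p = 1e-05, adjusted p = 3.33e-05), with rho = -0.31 within other introns (permutation p = 0.00011, adjusted p = 0.000367) and rho = -0.17 within ribosomal protein introns (permutation p = 0.130), a difference that was not tested. Mismatches in the 5′ splice site gave rho = -0.14 (permutation p = 0.0337, adjusted p = 0.0562) and r = -0.24 (permutation p = 0.0002, adjusted p = 0.0005) over all introns. Within other introns they gave rho = -0.31 (permutation p = 7e-05, adjusted p = 0.00035) and within ribosomal protein introns rho = -0.07 (permutation p = 0.522). The distance from branch point to 3′ splice site gave rho = 0.20 (permutation p = 0.00247, adjusted p = 0.00494) but r = 0.04 (permutation p = 0.525, adjusted p = 0.689), and it passed in neither class. The apparent rate followed log10 total reads most closely (rho = 0.70 and r = 0.69, both with permutation p = 1e-05 and adjusted p = 3.33e-05, 283 introns), and did so within each class (rho = 0.53 and 0.46). Total reads are also the denominator of the unspliced share to which the rate is fitted. Part of this relation may therefore be built in, and the permutations do not remove that part. The lariat ratio rose with log10 intron length (rho = 0.21, permutation p = 0.00243, adjusted p = 0.00494; r = 0.17, permutation p = 0.0137, adjusted p = 0.0273; 220 introns), and within each class it did not pass (rho = 0.16 and 0.13). The other 4 relations of the lariat ratio did not pass, with rho from -0.03 to 0.05. The smallest p here is again the smallest that the permutations can give, and introns are not independent replicates.

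The main question of the mutant series was whether the prp2-1 allele leaves more labelled RNA unspliced. In the 1 prp2-1 course, summed over these times, the typical intron had fewer unspliced reads than in WT, and a few introns had more. By library, the prp2-1 median lay below all WT courses at 150, 210, 390 and 540 s, and at their lower edge at 720 s. It lay within the WT range at 300 s (6.75% against 4.55 to 7.80%) and at 990 s (3.25% against 3.04 to 4.22%). Over 150 to 990 s the snoRNA gene SNR17B, 1 of the 2 U3 RNA genes, had 19.7% ± 3.93 unspliced reads in WT (SD, n = 3) and 1.87% in prp2-1 (interval 1.79 to 1.96%). The meiotic gene MND1 had 47.9% ± 8.32 and 10.8% (9.38 to 12.5%), RPS7A 27.5% ± 9.23 and 7.72% (7.42 to 8.02%), and ACT1 16.0% ± 1.58 and 8.76% (8.59 to 8.93%). In the other direction, DBP2, a DEAD-box RNA helicase gene, had 22.9% ± 5.27 in WT and 54.6% (52.2 to 57%) in prp2-1, and MCR1, the mitochondrial NADH-cytochrome b5 reductase gene, had 51.0% ± 1.34 and 76.9% (76.6 to 77.1%).

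By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 87 of 283 introns were lower and 6 higher in prp2-1, with a median log2 change of -0.62. The intron of SNR17B changed by -3.66 ± 0.38 (SE, adjusted p = 4.83e-05), that of MND1 by -2.94 ± 0.35 (adjusted p = 0.000147), and that of DBP2 by 2.04 ± 0.31 (adjusted p = 0.00126), all in edgeR's quasi-likelihood test. MCR1 changed by 1.68 ± 0.32 (adjusted p = 0.00555) in the same edgeR test. The other risers were PSP2 (0.91), SAC6 (0.70), RPL18B (2.74) and HMRA1 intron 1. HMRA1 intron 1 rests on 2 unspliced reads of 4 in prp2-1, where WT had 5.22% ± 0.662, and in RPL18B 98.9% of the prp2-1 unspliced reads ended between the branch point and the 3′ splice site. Large falls also came in SAE3 (-2.53), RPS30B (-2.50), RPS7A (-2.13), AMA1 (-2.12) and RPL7B intron 1 (-1.74). YPR202W was also lower (-2.03) but turned direction when libraries were thinned to the same depth. Ribosomal protein paralogs, the U3 gene SNR17B and YPR202W may share reads with their copies and are uncertain. Scaling each read state by TMM moved the median to -0.39 and the share of passing introns that were higher from 6.45% to 16.9%.

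Grouped by function, ribosomal protein introns were lower in 37 of 103 cases and higher in 1, RPL18B. Adjusted over the list alone, 41 passed. The meiotic list had 6 of 9 lower and none higher (7 adjusted over the list alone), with DMC1, the meiotic recombinase gene, at -1.65 beside MND1, SAE3 and AMA1. In the secretory list 8 of 19 were lower, for example ERD2, the HDEL receptor gene (-1.20), and YOP1 (-1.06), and the list alone gave the same count of 8, while TMM gave 5 lower and 1 higher. Translation factors were lower in 2 of 3 cases, TEF4 (-1.47) and ASC1 (-1.19), while EFB1 gave -0.46. The mitochondrial list split, with MRPL44 (-1.36) and QCR10 (-0.87) lower and MCR1 higher, and TMM gave 1 of each. The cytoskeleton list had ACT1 (-0.98) and MOB1 (-0.93) lower of 10, but neither passed when adjusted over the list alone, and with each read state scaled by TMM none was lower and 1 higher. RUB1 (-0.89) was lower as 1 of 8 ubiquitin pathway introns, where TMM gave none lower and 1 higher. In the RNA processing list DBP2 and PSP2 were higher and 8 did not pass. Of the genes that control their own expression, DBP2 was higher and 5 of 6 did not pass, with RPL30 at -0.75, YRA1 at -0.31 and RPS14B at -0.25. Among 19 introns of genes with more than 1 intron, 5 were lower and 1 higher, and TMM gave 3 lower and 2 higher. The SUS1 introns parted, with the second lower (66.9% ± 5.67 in WT and 41.5% in prp2-1, interval 39.0 to 44.0%) and the first at 40.3% ± 2.67 and 47.0% (45.7 to 48.3%) without passing. MTR2 (0.15), TUB1 (0.65), TUB3 (0.41) and GCR1 (-0.04) did not pass either.

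A test of whole lists with camera at a preset correlation of 0.01 put ribosomal protein introns lower than the rest (median -0.79 against -0.48, adjusted p = 0.00692) and RNA processing introns higher than the rest (median -0.25 against -0.65, adjusted p = 0.0350). Neither call held with an estimated correlation (adjusted p = 0.611 for both, with an estimated correlation). The mean of the RNA processing list was 0.04, so its mean and median differ in sign. Over 150, 210, 720 and 990 s camera gave adjusted p of 0.305 for ribosomal protein and 0.187 for RNA processing introns, and the latter also lost its call without WT replicate 1 (0.0875) or 3 (0.172). The other 8 lists had adjusted p from 0.234 to 0.788 in camera.

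**Figure D3:**
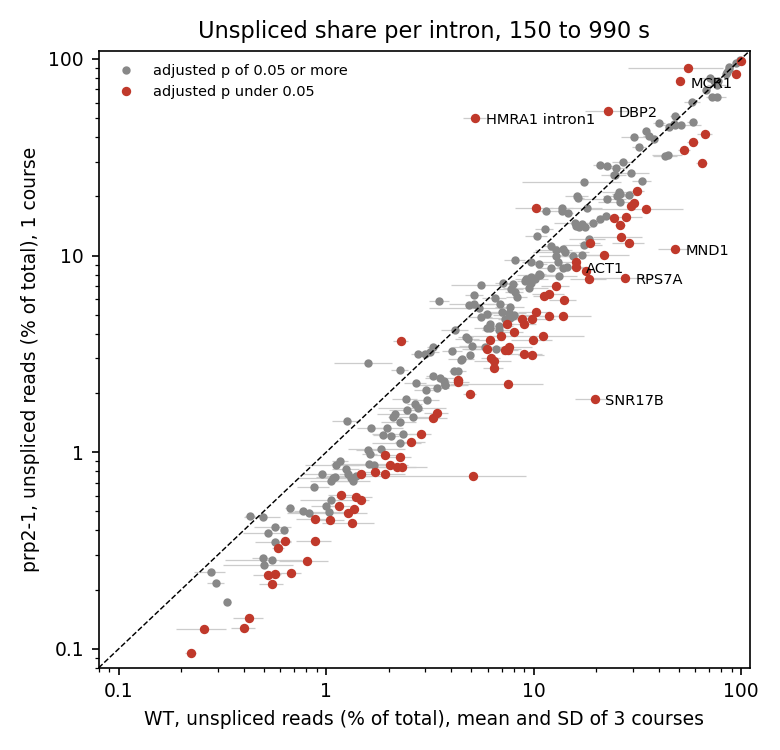
Unspliced reads as a percent of all reads per intron, WT on the x axis (mean of 3 courses, bars are the SD) and the 1 prp2-1 course on the y axis, both on log scales. Introns with an adjusted p under 0.05 in edgeR's quasi-likelihood test are red and the dashed line marks equal shares; 87 such introns lie lower and 6 higher in prp2-1.

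The strain difference rests on 1 course against 3, and the lone course is assumed to vary as the WT courses do. Values did not overlap for 86.6% of introns, where chance gives 50%. The median log2 change of -0.62 was -0.79 over 150, 210, 720 and 990 s, -0.61 over the early times and -0.09 over the late times. Leaving out WT replicate 1, 2 or 3 gave -0.65, -0.63 and -0.57. The 93 passing introns became 4 without WT replicate 2, 37 without WT replicate 3, 2 over 150, 210, 720 and 990 s, 11 over the late times, 22 over the early times, 20 with equal weight for each time (median -0.31), 28 by the deposited splicing index and 17 with every library thinned to the same depth (median -0.33).

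Prp2 acts before the first step, so the balance between lariat intermediate and other unspliced reads was compared as well. In MCR1 the lariat intermediate made up 21.7% ± 3.79 of unspliced reads in WT (SD, n = 3) and 67.1% (66.8 to 67.5%) in prp2-1. The share was also higher in RPS11A (30.2% ± 6.26 and 64.2%, interval 60.4 to 67.9%) and in RPL32 (10.1% ± 5.17 and 30.4%, interval 28.7 to 32.2%). In DBP2 it was 64.4% ± 8.52 in WT and 22.2% (19.6 to 25.1%) in prp2-1, and in RPL16B 70.7% ± 10.5 and 24.0% (21.5 to 26.7%). In TUB3, an alpha-tubulin gene, it was 18% ± 7.78 and 4.72% (3.97 to 5.60%). RPL34A had 6.09% ± 1.32 in WT and 0.207% (0.0365 to 1.16%) in prp2-1, which is 1 lariat read of 484, and GIM5 had 9.07% ± 2.05 and 0.844% (0.232 to 3.02%), which is 2 of 237. RPL18B, RPS25A (-1.95) and the fimbrin gene SAC6 (-1.83) were lower too. Without reads that ended between the branch point and the 3′ splice site, RPL32 (30.3% ± 1.75 and 46.6%, log2 change 1.01 ± 0.40), RPL18B (7.05% ± 1.88 and 4.71%, log2 change -0.59 ± 0.52), TUB3, RPS25A and SAC6 did not pass.

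By edgeR's quasi-likelihood test 3 of 261 introns were higher and 9 lower, with a median log2 change of -0.30. MCR1 changed by 2.90 ± 0.49 (SE, adjusted p = 0.00185), DBP2 by -2.69 ± 0.50 (adjusted p = 0.00218) and RPL16B by -2.99 ± 0.53 (adjusted p = 0.00185) in this edgeR test. Ribosomal protein introns were higher in 2 of 102 cases and lower in 4, and 8 passed when adjusted over the list alone. MCR1 was the one passing intron of 6 in the mitochondrial list, GIM5 of 18 in the secretory list (4 passed when adjusted over the list alone), TUB3 of 10 in the cytoskeleton list, and DBP2 of 6 self-regulated and of 10 RNA processing introns. In the meiotic, ubiquitin pathway, translation factor and multi-intron lists none passed, although 1 translation factor did when adjusted over its list alone. ACT1 had 35.8% ± 0.630 in WT and 32.7% (31.8 to 33.7%) in prp2-1, the second SUS1 intron 82.3% ± 2.96 and 79.0% (75.6 to 82.0%), and neither passed; RPS14B (-1.27), YRA1 (-1.17) and RPL30 (-0.72) did not pass either. No intron passed in edgeR with each read state scaled by TMM (median 0.03; 47 at an unadjusted p under 0.05), without a filter on low counts (38), over the early times (26) or without WT replicate 3 (30), against 49 in the fit reported here and 12 calls by DESeq2. The count was 1 by limma with equal weight for each time, 20 over the late times, 22 without WT replicate 1, 4 without WT replicate 2, 7 with reads that end past the branch point left out, 5 with raised count minimums and 4 over 150, 210, 720 and 990 s.

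Within the prp2-1 course the unspliced share also fell with labelling time. Late against early sums, 262 of 278 introns went down and the median log2 change was -0.95, with no replicate and so no test. The WT courses gave medians of -1.63, -1.58 and -1.35. With equal weight for each time the medians were -1.04 in prp2-1 and -1.36, -1.03 and -1.38 in WT, so the prp2-1 value lay within the WT range. For DBP2 the late minus early change was 0.98 in prp2-1 and -1.60 ± 0.44 in WT (SD, n = 3), and for RPS6A 0.41 and -2.46 ± 0.47, while ACT1 had -1.26 and -1.29 ± 0.23. No intron of 278 passed edgeR's quasi-likelihood test of the difference between the changes, where 17 had an unadjusted p under 0.05; DBP2 and RPS6A came closest, both with an adjusted p of 0.136. DESeq2 called 2 introns, limma none, and the fit with the time course as a block called 10, all higher in prp2-1. On simulated data this test found 3.33% of introns changed by a log2 of 1 and 6.90% of those changed by 2, so in that setting most changes of that size would be missed. Early and late sums of a simulated course were independent, whereas those of the WT courses were correlated.

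Apparent lifetimes were compared between the strains to ask which introns were removed faster or slower. The fits used all labelled times of a course, from 90 to 990 s in WT and from 120 to 1320 s in prp2-1. The mean WT median share rose from 18.8% at 90 s to 22.1% at 120 s, although in replicate 1 it went from 20.5% to 19.1%. The fitted curve can only fall, so it cannot follow such a rise. Strain and time range are thus mixed here, and no fit over shared times alone was run. In prp2-1 the median lifetime was 21.6 s over 283 introns, with 3.72 s in ribosomal protein introns and 42.7 s in the others. Unspliced DBP2 RNA lasted 64.2 s ± 12.6 in WT (SD, n = 3) and 567 s in prp2-1, and that of MCR1 322 s ± 50.2 and 1359 s. Shorter lifetimes were found for SNR17B (53.4 s ± 17.1 and 8.89 s), MND1 (288 s ± 102 and 56.7 s), RPL7B intron 1 (34.9 s ± 4.51 and 13 s) and AMA1 (452 s ± 64.4 and 183 s). By limma with Benjamini-Hochberg adjustment 5 introns of 283 were faster and 4 slower in prp2-1, with a median log2 difference of 0.20. The fifth faster intron was YPR202W (1.26) and the remaining slower ones were RPL18B (-2.26) and HMRA1 intron 1, which has 6 reads over the labelled prp2-1 libraries. ACT1 had 53.3 s ± 5.36 and 40.6 s, MTR2 2001 s ± 365 and 3407 s, and TUB3 21.4 s ± 3.70 and 32.2 s, and these did not pass. The 9 calls became 27 with times up to 400 s, 5 after background subtraction, 18 without WT replicate 1 and 31 without WT replicate 2.

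The next comparison asked which targets gave more or less labelled RNA in prp2-1, relative to the typical target, with cpm scaled to library totals and log2 changes to TMM factors as well, so the 2 differ in size. USV1, a stress-response transcription factor gene, had 94.0 ± 19.9 cpm in WT (SD, n = 3) and 7206 in prp2-1, a log2 change of 5.68 ± 0.24 (SE, adjusted p = 0.000230, edgeR's quasi-likelihood test). OM14, a mitochondrial outer membrane protein gene, was at 2957 ± 652 and 46976 cpm (3.40), CMC4 at 785 ± 142 and 12199 (3.37), and HAC1, the transcription factor of the unfolded protein response, at 638 ± 273 and 7705 (3.02). RRT8 (3.66), the meiotic REC114 (3.48), MRK1 (3.43) and QCR10 (2.84) complete the strongest risers, and of these 8 targets all but USV1 were lower when scaled to the spike-in RNAs. DBP2 went the other way, with 495 ± 179 and 126 cpm (-2.57 ± 0.48, adjusted p = 0.00677, edgeR's quasi-likelihood test), as did NOG2 (-2.66), RPS17B (-1.98), RPL7A intron 1 (-1.86), RPL31A (-1.77), RPL16A (-1.71) and RPL6B (-1.71). HMRA1 intron 1, in the silent copy of the mating-type gene a1 whose sequence is shared with the expressed copy, had 627 ± 107 cpm in WT and 4 reads in prp2-1 over the same times.

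In total 91 of 284 targets rose and 98 fell. Ribosomal protein targets fell in 89 of 103 cases (90 adjusted over the list alone) and none rose, among them RPL30 (-1.66) and RPS14B (-1.01). All 6 mitochondrial targets rose, for instance MRPL44 (2.64) and MCR1 (2.59), and 5 of 9 meiotic targets rose while 1 fell, with MND1 at 2.61 and AMA1 at 2.27; under spike-in scaling all 6 mitochondrial and 7 meiotic targets were lower. The secretory list had 10 of 20 higher and none lower, with YOP1 at 1.73 and SNC1 at 1.54, 7 passed when adjusted over the list alone, and 19 were lower under spike-in scaling. In the ubiquitin pathway 4 of 8 rose, UBC5 by 1.94, and all 8 were lower under spike-in scaling. ACT1 rose by 0.75, in a cytoskeleton list with 3 of 10 higher, of which none passed adjusted over the list alone and all 10 were lower under spike-in scaling, and TUB3 gave -0.40 without passing. Self-regulated genes fell in 5 of 6 cases, and in 3 by library totals alone. RNA processing targets had 2 higher and 3 lower of 10, and multi-intron targets 2 higher and 7 lower of 19, where library totals alone gave 5 higher and 1 lower, and 5 higher and 3 lower. Of the translation factors none of 3 passed, where DESeq2 gave 2 lower, and TEF4 (-0.48) and EFB1 (-0.54) gave negative values.

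Directions here depend on the scaling. By library totals alone the median shifted to 0.57 and 129 targets rose while 53 fell, a share of 70.9% higher instead of 48.1%. The spike-in RNAs gave 1141 to 1391 intron reads per spike-in read in the WT courses and 46.7 in prp2-1, and scaling to them put the median at -4.18, with 276 targets lower and USV1 alone higher. Of 103 ribosomal protein targets 89 passed as lower with TMM or RLE factors, 90 with DESeq2, 49 by library totals alone and 103 by the spike-in, and none as higher under any of these. All 6 mitochondrial targets were higher under the first 4 of these scalings and lower when scaled to the spike-in, where their median of -1.70 still lay above that of all targets.

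The 2 wild-type series were compared over 90, 120, 150 and 300 s, as shares within libraries, since their tables and spike-in RNAs differ. The question was whether the same introns keep their unspliced share. GLC7, the catalytic subunit of protein phosphatase 1, had 60.9% ± 12.3 unspliced reads in WT (SD, n = 3) and 0.394% ± 0.0291 in WT_30 (SD, n = 2). RPS6B had 0.521% ± 0.179 and 24.2% ± 3.94, SNR17A, the other U3 gene, 13.7% ± 0.983 and 86.3% ± 0.668, and the aminopeptidase gene APE2 23.3% ± 7.07 and 86.8% ± 0.925. The GLC7 intron lies on chromosome V 432672 to 433196 (plus strand) and that of RPS6B on chromosome II 592417 to 592768 (minus strand), each between coding exons. Reads of RPS6B and SNR17A may be shared with their copies.

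By edgeR's quasi-likelihood test 107 of 284 introns were higher in WT_30 and 80 lower, with a median log2 change of 0.32. GLC7 changed by -8.65 ± 0.43 and SNR17A by 5.32 ± 0.27 (SE, adjusted p = 8.42e-12 for both in edgeR), and RPS6B by 5.97 ± 0.33. Further rises came in RPS29B (4.45), RPL40B (3.91), RPL20A (3.85), SCS22 (3.65) and the ubiquitin-conjugating enzyme variant gene MMS2 (3.58), and further falls in RPL32 (-4.77), DMC1 (-4.69), RPS23A (-4.23), CGI121 (-4.16), EFB1 (-4.07), EFM5 intron 2 (-3.99) and RPL18B (-3.97). Ribosomal protein introns went both ways, 50 higher and 25 lower of 103 (76 adjusted over the list alone), as did secretory introns, 6 higher and 7 lower of 20, with ERD2 at 2.80 and YIP3 at -3.78. In the mitochondrial list 4 of 6 were higher, MRPL44 (2.15) and MCR1 (1.19) among them, and 1 was lower. Ubiquitin pathway introns were lower in 4 of 8 cases and higher in 1, with UBC5 at -1.89 and UBC4 at -1.41. Cytoskeleton introns were lower in 4 of 10, including TUB1 (-3.51) and ACT1 (26.1% ± 3.79 and 8.30% ± 1.74), while TUB3 (0.09) did not pass. Self-regulated genes were lower in 5 of 6, with RPL30 at -1.09, DBP2 at -0.91 and YRA1 at -0.84, and RPS14B higher at 1.21. RNA processing introns had 4 higher and 3 lower of 10, LSM2 at 1.93 and LSM7 at -1.97. Meiotic introns had 2 higher and 4 lower of 9, and translation factors 1 of each. Multi-intron genes had 2 higher and 7 lower of 19, with SUS1 intron 2 at -3.22 and intron 1 at -1.10. MTR2 was higher (1.48) and GCR1 (0.40) did not pass. HAC1, looked at after its values had been seen, had 67.9% ± 2.68 in WT and 89.7% ± 0.515 in WT_30.

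**Figure D4:**
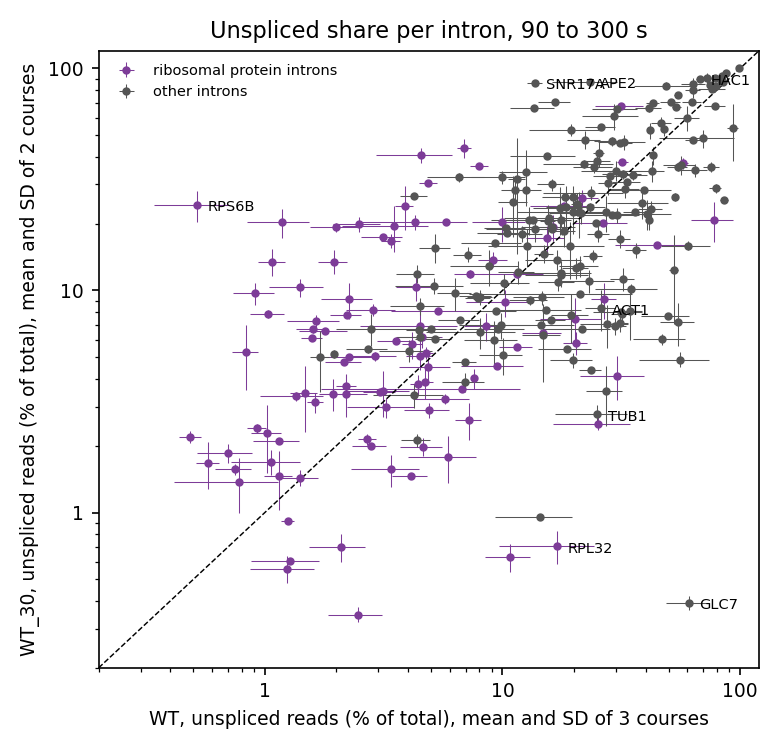
Unspliced reads as a percent of all reads per intron over 90 to 300 s, WT on the x axis (mean and SD of 3 courses) and WT_30 on the y axis (mean and SD of 2 courses), both on log scales, with ribosomal protein introns in purple. The dashed line marks equal shares; 107 introns were higher in WT_30 and 80 lower in edgeR's quasi-likelihood test.

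The same introns differed at 0 s, before any label was added. Across 233 introns, the WT_30 against WT difference at 0 s ranked introns as the labelled difference did (rho = 0.84 and r = 0.89, permutation p = 1e-05 for both, the smallest possible). These introns had a mean of at least 20 unspliced and 100 total reads over the 0 s libraries of both series pooled. The median intron had 5, 15 and 11 unspliced reads in the WT 0 s libraries and 152 and 98 in those of WT_30. The filter thus favours introns high in WT_30, and the WT side rests on few reads. The target HMRA1 intron 1, whose sequence the labelled strain's mating type expresses, had 304 to 7507 reads in each labelled WT library and 0 to 2 in each labelled WT_30 library. Values did not overlap for 79.2% of introns, where chance gives 20%. Scaling each read state by TMM moved the median to 0.10 and the calls to 100 higher and 100 lower, and of the ribosomal protein introns 47 were then higher and 30 lower.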

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

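All tests in this part were chosen after the result was seen, except that of the WT_30 series. In MTR2, 99.0631% ± 0.138 of the unspliced reads in labelled WT libraries ended between the branch point and the 3′ splice site (SD, n = 3), in a table that no comparison of the report uses by itself, and in the 0 s libraries 97.9% ± 0.565.

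Summed over 150 to 990 s, the prp2-1 course held fewer unspliced reads than WT in the typical intron, with a median log2 change of -0.62 (-0.09 over the late times). Its later libraries weigh more in the sums, but with every library thinned to the same depth the median was -0.33 (-0.334934), so this weighting could not be the whole cause, although the size was smaller. Whether unlabelled spliced RNA carried through the pull-down is the cause could not be judged. After subtracting the 0 s background the median difference of log2 rate was 0.24 (0.240885), against 0.20 without. That subtraction used 0 s reads as counted, without matching them by spike-in, so it may remove too little. The rates were also fitted over different times in the strains. The prp2-1 0 s libraries held 1.92 and 0.933 intron reads per spike-in read, and the 150 s library 6.37. Open are this carry-over, an effect of the allele, which was not tested, and any other difference between the series, which coincides with strain here.

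The unspliced share differed in both directions between WT_30 and WT. If the series counted or amplified unspliced and spliced reads differently, the same introns would differ without label, and the differences at 0 s and in labelled libraries did go together (rho = 0.839984, 233 introns, same sign in 84.1%). The WT side of the 0 s difference rests on few unspliced reads per intron. Within that limit this explanation has the values it needs, and a lasting difference between the cultures, which would also be seen at 0 s, stays open and untested.

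Most unspliced reads of RPL18B ended between branch point and 3′ splice site, 84.8% ± 11.4 in labelled WT libraries (SD, n = 3). Unlabelled RNA or primer products carried through the pull-down likely account for part, as the share at 0 s was 99.697% ± 0.333. No biological explanation was tested.

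For late against early sums in WT, the real split gave 254 introns and the highest of the other splits gave 0, so 1 of 10 splits gave as many. These splits are too few for a share under 0.05. The early and late sums of a course are pairs, and 4 of the splits, the real one included, part all 3 pairs; the others of these gave 0 at most, as did the 6 that part 1 pair. Within the courses 265 of 275, 260 of 273 and 262 of 273 introns went down.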

How the results depend on the processing

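Alternatives added after the data were seen are the deposited splicing index, the times 150, 210, 720 and 990 s, thinning, and leaving out reads past the branch point. Over all alternatives, whole comparisons counted as the same in 129 cases, moved in 33, and were weaker in 6, stronger in 3 and reversed in 1. For named introns and lists the counts were 1584 the same, 270 weaker, 19 stronger and 24 reversed. For a count of calls, the same means within 1.5 times the main count. For the late against early median of prp2-1 it means within the SD of the WT courses. For a single test it means that passing or not passing did not change, whatever the sign where neither passed. WT_30 against WT ran from 139 to 205 calls, labelled RNA from 173 to 277, and late against early WT from 194 to 262 except with TMM. The cause was not tested for any change below, except that fewer samples or reads enter when replicates are left out or libraries thinned.

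For unspliced prp2-1 vs WT (93 calls), limma on averaged ratios gave 20, late times 11, early times 22, the splicing index 28, the 4 times 2, thinning 17, and leaving out replicates 4 to 74; YPR202W was 0.24 when thinned. For the lariat intermediate (12), no filter, TMM and early times gave 0, raised minimums 5, limma 1, late times 20, reads past the branch point left out 7, the 4 times 4, and leaving out replicates 0 to 22. For late vs early WT, TMM gave 56, with ACT1 at 0.23, SUS1_intron1 0.51, SUS1_intron2 0.36, TUB3 0.14, RPL30 0.18, RPS14B 0.64, YRA1 1.16 and HAC1 1.48. The late-early change (0 calls in edgeR, 17 at an unadjusted p under 0.05) gave 2 by DESeq2, none by limma and 10 with the replicate block. Rates (9) gave 27 up to 400 s, 5 after background subtraction, and 12 to 31 without replicates. For labelled RNA under spike-in scaling RRT8 was -0.51, REC114 -0.66, MRK1 -0.76, OM14 -0.78, CMC4 -0.82, HAC1 -1.12, QCR10 -1.32, MRPL44 -1.54, MCR1 -1.58, MND1 -1.56, AMA1 -1.90, UBC5 -2.23, YOP1 -2.43 and SNC1 -2.61, and labelled RNA prp2-1 vs WT: ACT1 was -3.42. Late vs early prp2-1 was -1.34 over the 4 times. The lariat difference of ribosomal protein introns (0.71) was 0.94 without a filter, 0.26 with raised minimums, 0.36 over late times and 0.62 to 0.77 without replicates. List tests (2 lists) gave 0 with an estimated correlation, 1 over the 4 times (the meiotic list, neither of the 2 reported) and 1 to 2 without replicates (ribosomal protein introns in each). Of 10 feature relations 5 passed over all introns, 1 within ribosomal protein introns and 3 within others, of which 2 were among the 5. In these classes, rate with length was -0.15 and 0.0179, with branch to 3′ splice site 0.12 and 0.0189, with branch mismatches -0.17 in the former, with 5′ splice site mismatches -0.31 in the latter, and lariat ratio with length 0.16 and 0.13.

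The replicate block gave 262 calls against 254 for late vs early WT and, apart from the late-early change, moved no count by over 1.5 times. WT_30 and WT share only numbers (correlation 0.0813), and a block gave 185 against 187. No paired analysis was possible because prp2-1 and WT share fewer than 2 numbers, which holds for unspliced reads, lariat, rates, labelled RNA and lists. Spliced reads from the splicing index could not be taken, since it holds the ratio alone. For late vs early prp2-1, DESeq2, limma, TMM, leaving out replicates and a block were not run, as it has 1 course. Depth limits the prp2-1 0 s libraries and the introns with few reads.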

Other observations

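HMRA1 intron 1, a check of mating type fixed beforehand, had 304 to 7507 total reads in each of the 27 labelled WT libraries. It had 0 to 2 reads in each of 18 labelled WT_30 libraries, although both series carry the strain label BY4741, and 0 to 2 in each of 9 labelled prp2-1 libraries.

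HAC1, whose intron is removed without the spliceosome, was followed by library. It was 69.99% ± 3.70 unspliced at 150 s and 65.4% ± 1.82 at 990 s in WT (SD, n = 3), 71.8% and 69.3% in the prp2-1 course, and 89.3% ± 0.231 at 150 s and 89.7% ± 0.135 at 3600 s in WT_30 (SD, n = 2).

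Reads ending between branch point and 3′ splice site also made up large parts of the unspliced reads of COF1 (76.5% ± 4.69, SD, n = 3), RPL24B (72.4% ± 12.4), RPL28 (68.3% ± 8.19) and RPL32 (66.7% ± 17.2) in labelled WT libraries. These introns were looked at after their values had been seen.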
